A study of Homo sapiens with 6 samples.

How the data were processed

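RNA from 2 human lung adenocarcinoma lines was measured on 1-colour Agilent arrays that carried probes for long noncoding RNAs and mRNAs. A549 is an established lung adenocarcinoma line that is sensitive to cisplatin, and A549/CDDP is a cisplatin-resistant line that was kept in 2 mg/L cisplatin. Each line had 3 arrays, and the series describes the 3 as independent experiments. Per the labels' protocols, total RNA was extracted with Trizol and labelled with the Agilent Quick Amp kit. The cultures behind the arrays are not described further, so p-values measure the spread between these 3 experiments of each line.

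Per the file headers, the authors' intensity values came from Agilent Feature Extraction version 10.7.3.1, with 1 scanner file per array. The deposited processed intensity of a spot is its brightness after background subtraction and detrending within the array, with low values set to a floor and no scaling between arrays. The headers give 1 scan identifier for all 6 arrays, so slide and scan could not be set as a block. The positions of the spots put the 6 arrays in a grid of 2 rows and 3 columns, where column 1 held A549 only, column 2 held A549/CDDP only and column 3 held 1 array of each line.

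The authors' value table held deposited intensity values for 34241 probes, and its columns were set against the scanner files to find their scale. All 34241 probes were found there, the median ratio to the processed intensity was 1.00 on each array, and the lowest value was 5. Its values were linear and neither scaled between arrays nor centred, with column medians of 114, 120, 146, 89.8, 161 and 157 in the order A549 replicates 1 to 3 and A549/CDDP replicates 1 to 3. Of its probes, 34239 were well above background on at least 1 array, and the table's own selection rule is not given in the sources used here.

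Each scanner file held 62738 spots. The 1319 control spots, 600 negative-control spots and 12 to 46 spots per array with outlier flags were left out, and spots of one probe were averaged, which left 60639 probes. No spot used was marked as saturated. The log2 processed intensity minus the array's 75th percentile was the measured level. A probe was tested where it was well above background on all 3 arrays of at least 1 line, and 27393 probes passed. limma (version 3.58.1, in R 4.3.3) fitted the 2 lines with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all tested probes counted as changed. Where a probe was well above background on every array of one line and on no array of the other, the brighter line's mean was set against the dimmer line's mean of, per array, the higher of the lowest level well above background and the probe's own level, which gives the "at least" folds.

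Of the 60639 probes, 59273 had only the maker's ID, which neither the files nor the tables at hand pair with a gene. These probes could not be split into mRNA and noncoding RNA, and no chromosomal distribution of changed genes was computed. The 9 names fixed beforehand as always to be given (ABCB1, ABCC2, ATP7B, SLC31A1, ERCC1, GSTP1, CDKN1A, NKD2 and AK126698) had no probe under their name. The probes with names were 93 exon and 53 intron probes of HOX transcripts and their neighbour PRAC1, 213 noncoding probes of the HOX clusters, 962 ultraconserved region probes, 20 reference mRNAs and 25 other transcripts. Of 65 transcript accessions in these names, 63 were matched to a gene symbol through a RefSeq table of assembly GRCh38.p14, used for names alone because the array's grid was built on hg19. An mRNA gene was represented by its probe of highest mean level.

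Comparisons, alternatives and 34 gene lists were fixed before the data were examined. The rule for named genes took the largest non-overlapping changes past the threshold among probes well above background on all 6 arrays, the largest bounds, and up to 4 members of a tested list. For probes without a gene name it was limited to 2 rises and 2 falls. Named probes outside this rule, the grouping of probes by HOX cluster and the comparison of exons were chosen after the values were seen. Only the housekeeping list had at least 5 tested members; the other 33 lists had fewer and were not tested. The value of 1 member of the housekeeping list is not reported here. Groups of probes were tested with camera (preset correlation 0.01, and an estimated correlation), and with fry. The pairing of HOX noncoding probes with the coding gene in their name was tested against 10000 re-pairings.

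In data simulated for the A549/CDDP against A549 comparison over 27325 probes, the fit recovered 56.0% of 100 probes changed by 2 on the log2 scale and 4.0% of 100 probes changed by 1, with 3 calls among unchanged probes. In this simulation most changes of 2-fold were missed. It changed far fewer probes than passed in the real comparison, which makes the adjustment stricter, and the number of arrays was not varied. The recovered shares therefore do not measure the power of the real comparison, and changes near 2-fold may still be missed. The alternatives were quantile normalization, median centring, normexp background correction (offset 50, on the median spot signal because the files give no mean signal), other filters, the value table, a replicate block, another variance model, a stricter threshold and leaving out each array. Blocks for the slide's rows and columns, the unscaled value table, another percentile and the flagged spots were added after the data were seen.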

Results

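RNA levels of the cisplatin-sensitive line A549 and the cisplatin-resistant line A549/CDDP were compared on 6 arrays, 3 per line, to find transcripts whose level differs between the lines. The labels give cisplatin in the medium for A549/CDDP only. A trait of the resistant line therefore cannot be told apart from a response to the drug. Between 42.2% and 50.2% of the 60639 probes were well above background on an array. The 75th percentile of the processed intensity, which was brought to 1 level before the comparison, ran from 124 on A549/CDDP replicate 1 to 215 on A549/CDDP replicate 2.

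The lines differed at 1100 of 27393 tested probes, of which 401 were higher and 699 lower in A549/CDDP. At 962 of these the difference was at least 2-fold, with 337 higher and 625 lower. Among probes without a gene name that were well above background on all 6 arrays and whose lines did not overlap, the 2 largest falls and the 2 largest rises were as follows. ASHG19A3A047282 fell by 6.04 ± 0.17 on the log2 scale (SE, n = 3 per line, limma adjusted p = 6.84e-05), and ASHG19A3A024216 fell by 5.15 ± 0.32 (adjusted p = 0.000745). ASHG19A3A039704 rose by 3.51 ± 0.19 (adjusted p = 0.000483) and ASHG19A3A046961 by 3.28 ± 0.23 (adjusted p = 0.00102). Over all tested probes 7330, or 26.8%, had lines that did not overlap, where chance gives 10%. Among the tested probes, 241 were well above background on all A549/CDDP arrays and on no A549 array, and 258 showed the opposite; 95 and 147 of them are among the 1100, with bounds of up to at least 46.2-fold higher and at least 23.8-fold lower in A549/CDDP.

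The arrays of A549/CDDP were less alike than those of A549. Over tested probes, the A549 arrays correlated with one another at 0.971 to 0.986. A549/CDDP replicate 2 correlated at 0.959 to 0.964 with the A549 arrays, and at 0.940 and 0.959 with replicates 1 and 3 of its own line. On the first principal component, which held 52.8% of the variance, it stood at -5.80, between the A549 arrays (-63.0 to -47.4) and the other A549/CDDP arrays (65.6 and 98.9). Component 2 held 20.7% and split both lines. A549 replicates 1 and 2 and A549/CDDP replicate 1 stood at 40.6, 33.8 and 38.5. A549 replicate 3 and A549/CDDP replicates 2 and 3 stood at -26.4, -52.8 and -33.7. The former arrays were dimmer, with a 75th percentile of 156, 162 and 124, against 196, 215 and 213. The cause of that split was not tested. Without A549/CDDP replicate 2, 3465 probes passed the test, 1560 higher and 1905 lower, and 1088 of them were among the 1100. The count was 339 without A549 replicate 1, 300 without A549 replicate 2, 574 without A549/CDDP replicate 1 and 460 without A549/CDDP replicate 3. With the array's row on the slide as a block 598 probes passed, and with its column as a block 1 probe did, with 3084 at an unadjusted p under 0.05. Only column 3 held both lines, so the difference between the lines in that fit comes from 1 array of each.

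**Figure D1:**
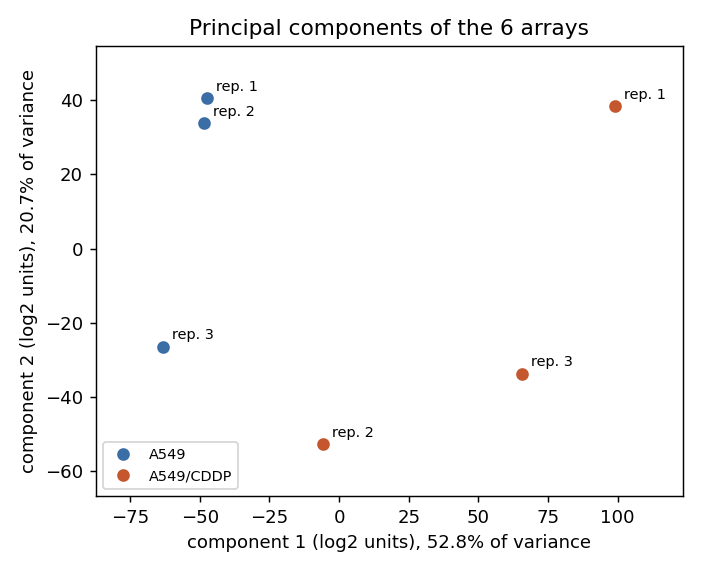
Principal components of the 6 arrays over 27325 tested probes, with component 1 on the horizontal and component 2 on the vertical axis, both in log2 units; each point is 1 array, coloured by line. A549/CDDP replicate 2 lies at -5.80 on component 1, between the A549 arrays and the other A549/CDDP arrays at 65.6 and 98.9. Component 2 sets A549 replicates 1 and 2 and A549/CDDP replicate 1 apart from the other arrays.

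Among mRNAs with a name, 5 HOX genes were lower in A549/CDDP, each read by its exon 2 probe. Exon 1 did not pass for HOXC10 (-0.29, limma adjusted p = 0.417) or HOXB13 (-0.26, adjusted p = 0.560). The falls are therefore those of exon 2 probes, and are not shown for the whole transcripts. HOX genes encode homeodomain transcription factors that set position along the body axis, and lie in the 4 clusters HOXA, HOXB, HOXC and HOXD. Of 47 named mRNA genes tested, 28 were HOX genes, 1 was PRAC1 and 18 were reference mRNAs; 5 fell, all of them HOX genes, and none rose. HOXC10 (NM_017409, exon 2) fell by 1.31 ± 0.18 on the log2 scale (SE, n = 3 per line, limma adjusted p = 0.0131), from 0.98 ± 0.07 (SD) in A549 to -0.33 ± 0.22 in A549/CDDP, relative to the array's 75th percentile. HOXB13 (NM_006361, exon 2) fell by 1.21 ± 0.19 (adjusted p = 0.0194) and HOXC11 (NM_014212, exon 2) by 1.14 ± 0.22 (adjusted p = 0.0402). HOXA2 (NM_006735, exon 2) fell by 1.09 ± 0.17 (adjusted p = 0.0208) and HOXB8 (NM_024016, exon 2) by 1.06 ± 0.19 (adjusted p = 0.0317). In each of the 5, all A549/CDDP arrays lay below all A549 arrays. The HOX falls were close to the limit of the test: none of the 5 passed without A549 replicate 1 or without A549 replicate 2, 1 gene passed without A549 replicate 3, A549/CDDP replicate 1 or A549/CDDP replicate 3, and 8 named mRNA genes passed without A549/CDDP replicate 2, 7 lower and 1, PGK1, higher. With normexp background correction HOXB8 differed by -0.59 (adjusted p = 0.114) and HOXC11 by -0.55 (adjusted p = 0.131), and neither passed. HOXC11 was also lost with median centring (-1.17, adjusted p = 0.0603) and with the trended and robust variance (adjusted p = 0.0637). Of 19 alternatives, the call was lost under 5 for HOXC10, 10 for HOXB13, 10 for HOXA2, 11 for HOXB8 and 13 for HOXC11. No named mRNA gene passed with the slide column as a block, and 1 did with the row.

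Exon by exon, 6 of 46 exon probes fell and none rose. The sixth was exon 2 of HOXB2 (NM_002145), which fell by 1.26 ± 0.21 (adjusted p = 0.0238), and differed by -0.58 with normexp background correction (adjusted p = 0.0780). Exon 1 of HOXB2, the brighter probe that represented the gene, differed by -0.36 ± 0.28 (unadjusted p = 0.244). All 6 were exon 2 probes, of 23 tested, against none of the 17 exon 1 probes and none of 6 probes on later exons. Some probes on other exons lay lower just short of the threshold. They were exon 1 of HOXB7 (-0.98, limma adjusted p = 0.0886), exon 4 of HOXB3 (-0.83, 0.0609) and exon 4 of HOXC4 (-0.73, 0.0781). Exon 1 of HOXA11 differed the other way (1.48, 0.167). The count of calls alone therefore does not set exon 2 apart. For HOXC10 exon 1 differed by -0.29 ± 0.18 (adjusted p = 0.417), and the difference between its exons was -1.03 ± 0.36 (adjusted p = 0.0418 over 9 transcripts with both exons tested). For HOXB13 exon 1 differed by -0.26 ± 0.24, and the exons by -0.96 ± 0.39 (adjusted p = 0.0636). HOXB7 and HOXA7 went the other way, with exon 2 above exon 1 by 1.11 ± 0.37 and 1.11 ± 0.38 (adjusted p = 0.0418 for both). Over the 9 transcripts the mean difference of exon 2 from exon 1 was smaller than its spread (-0.13 ± 0.91, SD; exact two-sided sign-flip permutation p = 0.672).

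**Figure D2:**
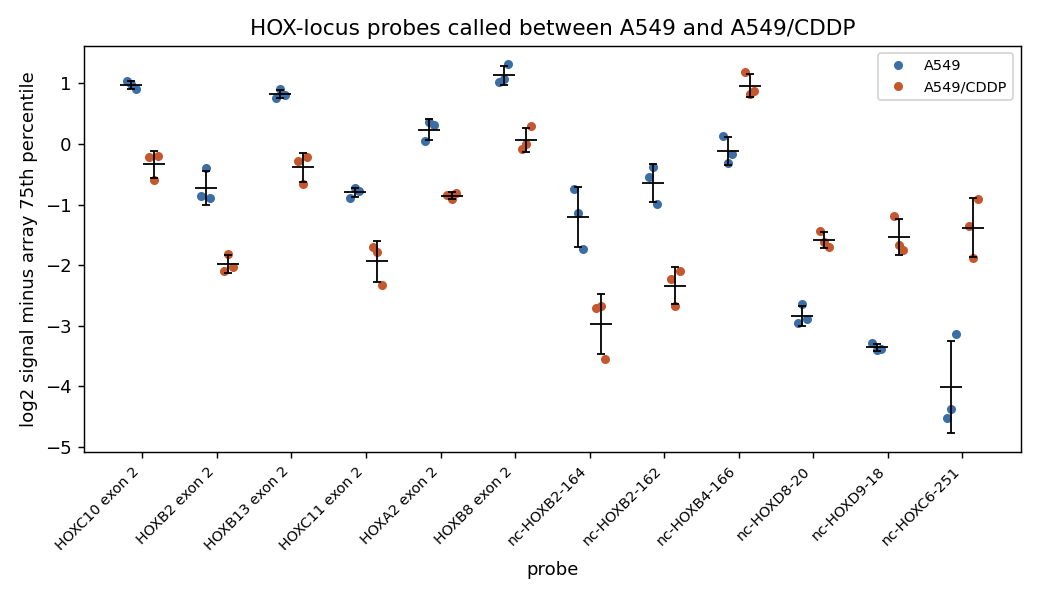
Level of the 12 HOX-locus probes past the threshold, as log2 signal minus the array's 75th percentile on the vertical axis and by probe on the horizontal axis; points are arrays (3 per line), and black bars are the mean and SD of a line. The 6 exon 2 probes are lower in A549/CDDP by 1.06 to 1.31 on the log2 scale, and of the 6 noncoding probes 4 are higher and 2 lower.

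By cluster, exon probes of HOXB and HOXC lay lower in A549/CDDP than other probes with camera's preset correlation, and not with an estimated correlation (adjusted p = 0.194 for both). Of 16 HOXB exon probes 15 had a lower mean in A549/CDDP and 3 fell, with a median log2 difference of -0.32 (camera adjusted p = 0.00126 over 12 groups of probes). Of 11 HOXC exon probes 10 had a lower mean and 2 fell, with a median of -0.42 (camera adjusted p = 0.00436). Both groups kept their direction under each scaling tried. fry, which asks whether a group's probes move one way on balance, gave adjusted p = 0.0161 for HOXB and 0.0216 for HOXC. HOXA exon probes had a median of 0.30, with 10 of 13 means higher in A549/CDDP (camera adjusted p = 0.370), and within that cluster HOXA2 fell while HOXA7 differed by 0.70 ± 0.18 (adjusted p = 0.101) and HOXA11 by 1.48 ± 0.49 (adjusted p = 0.167). Only 4 HOXD exon probes were tested, too few for a group. None of 17 HOX intron probes passed in limma, and 6 had an unadjusted p under 0.05.

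Noncoding transcripts of the HOX clusters changed in both directions. Of 118 named noncoding transcripts tested, 112 of them from the HOX clusters, 4 rose and 2 fell, all from the HOX clusters. That is 5.4% of the HOX cluster noncoding probes, near the 4.0% past the threshold over all tested probes. nc-HOXB4-166 rose by 1.08 ± 0.20 on the log2 scale (SE, n = 3 per line, limma adjusted p = 0.0378) and was the only one of the 6 that was well above background on all 6 arrays. nc-HOXD9-18 was not well above background on any A549 array and was at least 2.12-fold higher in A549/CDDP (adjusted p = 0.00587). nc-HOXD8-20, from the same cluster, was at least 2.05-fold higher (adjusted p = 0.0147), and nc-HOXC6-251 at least 2.36-fold higher (adjusted p = 0.0232). nc-HOXB2-164 was not well above background on any A549/CDDP array and was at least 2.56-fold lower there (adjusted p = 0.0431). nc-HOXB2-162 fell by 1.70 ± 0.25 (adjusted p = 0.0158) and was well above background on 1 of the 3 A549/CDDP arrays. As groups, the noncoding probes of no cluster passed camera's test, and those of HOXD, with 16 of 24 means higher in A549/CDDP, came nearest (adjusted p = 0.202). The number of noncoding transcripts past the threshold was 1 without A549 replicate 1, A549 replicate 2 or A549/CDDP replicate 1, 2 without A549/CDDP replicate 3 and 25 without A549/CDDP replicate 2. It was 0 with the slide column as a block and 3 with the row. With normexp background correction nc-HOXB4-166 alone passed, and the log2 difference was 0.43 for nc-HOXD9-18 (adjusted p = 0.207), 0.39 for nc-HOXD8-20 (0.197), 0.66 for nc-HOXC6-251 (0.0837), -0.61 for nc-HOXB2-164 (0.138) and -0.66 for nc-HOXB2-162 (0.0508). The offset of 50 in that setting shrinks the log2 differences of dim probes, so these values can lie below the bounds given above. The call of nc-HOXB4-166 was lost under 11 of 19 alternatives, median centring among them (1.05, adjusted p = 0.0962). Of 18 alternatives, the call was lost under 2 for nc-HOXD9-18, 7 for nc-HOXC6-251, 8 for nc-HOXB2-162, 10 for nc-HOXD8-20 and 10 for nc-HOXB2-164.

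The other noncoding RNAs with names did not pass. TncRNA differed by -0.64 ± 0.23 (adjusted p = 0.200) and mascRNA, a tRNA-like RNA cut from the MALAT1 transcript, by -0.82 ± 0.35 (adjusted p = 0.260). HOTAIRM1, a noncoding RNA of the HOXA cluster, differed by 0.32 ± 0.17 (adjusted p = 0.342). Among transcripts given only by an Ensembl name, ENST00000523627 rose by 1.20 ± 0.24 (adjusted p = 0.0439), a call that was lost under 11 of 19 alternative settings (adjusted p from 0.0336 to 0.557). These included leaving out any single array except A549/CDDP replicate 2, with adjusted p of 0.188, 0.193 and 0.0763 without A549 replicates 1, 2 and 3, and 0.0642 and 0.110 without A549/CDDP replicates 1 and 3.

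No relation was detected between HOX noncoding transcripts and the coding gene in their name. Over 79 pairs of a noncoding probe with one of 22 HOX genes, the changes, with the gene taken as the mean of its exon probes, correlated at a Spearman rho of -0.02 across pairs, which are not independent replicates (permutation p = 0.860 from 10000 re-pairings), and 35 pairs had the same direction. By the probe that represents each gene, no pair had both members past the threshold. Counting any exon probe of the gene there were 2, both lower: nc-HOXB2-162 and nc-HOXB2-164 with exon 2 of HOXB2.

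Ultraconserved regions, genomic segments that are identical in human, mouse and rat, were mostly not detected. Of 962 such probes 149, from 139 of 481 regions, were tested, and 1 passed. uc.266+ was not well above background on any A549 array and was at least 2.15-fold higher in A549/CDDP (limma adjusted p = 0.0347); its spot on A549/CDDP replicate 2 had an outlier flag and was left out, so the value rests on 5 arrays, and its size depends on that spot. The log2 difference was 1.40 without it and 3.93 with the flagged spots kept (adjusted p = 0.320), and 0.44 with normexp background correction (adjusted p = 0.205). These differences are taken against A549 levels not well above background. The offset of 50 in normexp shrinks differences of dim probes, so 0.44 can lie below the bound. At an unadjusted p under 0.05 there were 24. uc.340- had the largest positive log2 difference, 1.69 ± 0.42 (adjusted p = 0.0852). Without A549/CDDP replicate 2, 26 ultraconserved probes passed, 14 higher and 12 lower, and none passed without A549 replicate 1, A549 replicate 2, A549/CDDP replicate 1 or A549/CDDP replicate 3.

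Reference mRNAs showed no change past the threshold. None of 18 passed in limma, and 1 had an unadjusted p under 0.05. In the housekeeping list, the 5 tested genes had a mean log2 difference of 0.23 (camera p = 0.232, and p = 0.290 with an estimated correlation; fry p = 0.0348), and 1 passed when adjusted over the list alone. PGK1, a glycolytic enzyme, differed by 0.75 ± 0.19 (adjusted p = 0.0868), and passed under 3 of 19 alternative settings. ACTB differed by 0.24 ± 0.23 and GAPDH by -0.06 ± 0.17, with adjusted p of 0.584 and 0.855.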

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

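Of the tests below, those of the label, the RNA mixture, the slide column and the brightness of exon 1 were chosen after the result was seen. Groups of 3 arrays are too small for a test of outlying samples, and of 56 control-spot probes 11 were well above background on any array and none was at least 2-fold higher on every A549/CDDP array than on every A549 array.

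A549/CDDP replicate 2 lay between the lines. At 191 probes lower by over 2 on the log2 scale in both other A549/CDDP arrays than in every A549 array, 55.5% had fallen over 90% of the way in replicate 2, against 59.7% and 68.5% in the same comparison for replicates 1 and 3, which argues against an A549 culture under a wrong label. Another 45 of the 191 stood at the A549 level in replicate 2 (under 25% of the way), against 0 probes for replicates 1 and 3; 24.1% would need an A549 share over 0.5 and 68.1% a share under 0.1, so one admixture of A549 RNA cannot account for all of them. A549 replicate 3, in the same slide column, deviated with a slope of 0.071 on the deviation of replicate 2 over 817 probes (correlation 0.288). The sign was the same at 73.9% of them. That leaves room for a small effect of column 3 and argues against such an effect as the whole cause. The slope sets column 3 against column 1 in A549 and against column 2 in A549/CDDP. An effect of column 2, which held A549/CDDP only, would not show in it, so the slide column is not excluded. A difference between cultures of the resistant line may remain, and was not tested.

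The HOX falls past the threshold were all on exon 2 probes. The tested exon 1 probes of 3 of the 6 transcripts (HOXC10, HOXB2 and HOXB13) were all 3 well above background on all 6 arrays, which argues against exon 1 being too dim in these. The other transcripts had no tested exon 1 probe. Dim probes were not tested, so exon 1 may have been too dim in those. Exon 2 carries the homeobox, which HOX genes share, so probes there could also bind a paralog. If the 6 probes read one shared target they would deviate together within the lines, and their mean pairwise correlation was 0.0360, against a median of 0.0695 and a 95th percentile of 0.433 for random sets of called falling probes. That value lies well inside the spread of the random sets, so cross-hybridisation cannot be told apart from a change in the transcripts with 6 arrays. The exon probes of HOXC10 did change unequally (difference -1.03, limma adjusted p = 0.0418). An equal fall along the whole transcript would not give that if both probes respond alike, which was not tested. HOXB7 and HOXA7 had gaps as large in the other direction (1.11 for each, adjusted p = 0.0418). Cross-hybridisation or a change in part of the transcript could each give the gap of HOXC10, and so could probes that respond unequally. For HOXB2 and HOXB13 the difference was -0.90 and -0.96 and did not pass (limma adjusted p = 0.0636 for both).

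More probes fell than rose in A549/CDDP, with 36.5% of those past the threshold higher. Under 5 other scalings the share ran from 29.2% to 38.8%, so the choice among these scalings did not make the imbalance. They shifted the median of all probes by only -0.03 to 0.07, so they cannot decide about a larger error of scaling. Without the dimmest array, A549/CDDP replicate 1, it was 27.2%. It was also 27.1% without A549 replicate 1, 26.7% without A549 replicate 2, 37.5% without A549 replicate 3 and 22.2% without A549/CDDP replicate 3. At adjusted p under 0.01 it was 24.9%. Leaving out several other arrays thus lowered the share as much, so the 27.2% cannot decide about the dimmest array. Without A549/CDDP replicate 2 the share was 45.02%, with 1560 probes higher and 1905 lower. A biological explanation was not tested.

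The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 1100 probes, 5 mRNA genes, 6 noncoding transcripts, 6 HOX exon probes and 1 ultraconserved probe, and the highest of the other splits gave 0 for each in limma. At an unadjusted p under 0.05 the real split gave 5363, 10, 24, 15 and 24, and the highest of the others 3067, 6, 20, 7 and 30. The smallest camera p of another split was 0.000993 for HOXB exon probes, against 0.000105, and 0.00145 for HOXC exon probes, against 0.000727. The grouping by HOX cluster was chosen after the values of the real split were seen, so this order of the splits is no separate support. For the housekeeping list 2 of the 10 splits, the real one included, gave a p of 0.232 or less, and the smallest was 0.110.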

How the results depend on the processing

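Blocks for the slide's rows and columns, the unscaled value table, the percentile over detected probes and the keeping of flagged spots were chosen after seeing the data; the other settings were planned. The 1100 changed probes became 591 with no filter on dim probes, 358 at adjusted p under 0.01, 317 with the unscaled value table, 598 with the row block and 1 with the column block, and 300 to 3465 when single arrays were left out. In that order named mRNA genes, 5 in the main setting, numbered 1, 0, 0, 1 and 0 (0 to 8), noncoding transcripts, 6 in the main setting, 3, 1, 1, 3 and 0 (1 to 25), and HOX exon probes, also 6, 1, 0, 0, 1 and 0 (0 to 8). Noncoding transcripts numbered 1 under normexp and 1 among probes well above background on all 6 arrays. Ultraconserved probes, 1 in the main setting, numbered 2 under median centring, normexp and the percentile over detected probes, and 0 with no filter, at adjusted p under 0.01, with the column block and with flagged spots kept (0 to 26 with single arrays left out). Where limma gave 0, between 7 and 53 items of that class had an unadjusted p under 0.05. The cause was not tested, except that stricter thresholds, fewer arrays and added blocks leave the test less power by construction. By construction too, the offset of 50 in normexp shrinks the log2 differences of dim probes.

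HOXB and HOXC exon probes kept their direction and stayed past an unadjusted 0.05 in all 20 alternatives (highest camera p 0.0201 and 0.0324), 1 of which, the variance model, does not enter camera. Both highest p came with the estimated correlation, and neither group passed there once adjusted over the 12 groups (camera adjusted p = 0.194 for both). The housekeeping list stayed on its side in all 20 (p from 0.138 to 0.601). The rho of the HOX pairs stayed within -0.11 to 0.05, and turned positive with the row block (0.0061) and the column block (0.050), with -0.065 to 0.021 when single arrays were left out. The scalings shifted the median of all probes by -0.03 to 0.07. Over 26 followed probes and 487 values, 342 kept direction and side, 136 kept the direction and no longer passed, 3 newly passed and 6 turned sign. These were ACTB with the column block (-0.060), GAPDH without A549/CDDP replicate 1 (0.019; -0.13 to 0.019 when single arrays were left out), and RPS18 under quantile normalization (-0.0015), without A549 replicate 1 (-0.031), without A549/CDDP replicate 3 (-0.068; range -0.068 to 0.29) and with the column block (-0.10).

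No clear pairing by replicate number was seen. Deviations of same-numbered arrays correlated at 0.313, -0.177 and 0.0980. Of 6 arrays, 3 correlated best with their own number among the 3 arrays of the other line. So few arrays can neither show nor exclude a pairing. With the replicate number as a block 393 probes passed, with 0 mRNA genes, 3 noncoding transcripts, 0 HOX exon probes and 0 ultraconserved probes. A block for slide or scan was not run, since all arrays shared 1 scan. No chromosomal distribution was computed under any setting. Of ultraconserved probes 15.5% were bright enough to be tested, against 45.2% of all probes.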

Other observations

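Probes on the 2 strands of an ultraconserved region could both be tested in 10 regions, and their changes correlated at a Spearman rho of 0.39 (permutation p = 0.266 from 10000 re-pairings). The strands were tested about equally often, 73 plus and 76 minus.

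Among HOX intron probes, the one named intron 2 of HOXB4 was well above background on all A549 arrays and on no A549/CDDP array. It was at least 1.75-fold lower in A549/CDDP (limma adjusted p = 0.163), while nc-HOXB4-166, named for the same gene, rose. The probe named intron 2 of HOXA13 differed by 0.82 ± 0.21 (adjusted p = 0.0861). These numbers are part of the probe names and were not checked against the structure of the genes. Neither intron probe passed the test, and both were chosen after their values were seen.

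Of the 45 probes at which A549/CDDP replicate 2 kept the A549 level, 1 had a name, uc.210-. Its log2 difference over all arrays was -1.89 ± 0.77 (adjusted p = 0.239).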
